A study of Homo sapiens with 67 samples.

How the data were processed

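The series holds RNA sequencing of CD34-positive cells that were enriched with magnetic beads from human bone marrow aspirates. Per the labels' protocols, 5 to 10 ng of total RNA per sample was amplified with the SMARTer Ultra Low kit and sequenced on a HiSeq 2000. The labels give 23 healthy libraries, 24 libraries of an MDS stage called sMDS and 20 of a stage called tMDS, where MDS stands for myelodysplastic syndrome. The labels do not spell out sMDS and tMDS, so these names are used as they stand. No label gives a batch, a date of sequencing or another covariate for a model.

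The submitters' processing notes name STAR, TopHat2 and edgeR, and the builds hg19 and GRCh37, without versions and without saying which step each was used for. The deposited gene table has 21115 rows named by gene symbol and holds signal values, which are non-negative, not whole numbers and on a common library scale set by the authors. Its zeros appear as small positive values in 30 of the 67 libraries. Whole reads could not be recovered from these values, so no test for counts was used. The deposited isoform table has 49772 rows named by RefSeq transcript and holds FPKM values, which are normalised to transcript length and library size as estimated by the authors. The program that estimated them is not stated. The tables give no coordinates, and none are printed. Neither the counting program nor its use of strand is stated, so a gene and an overlapping antisense gene cannot be told apart in these values.

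The library totals of the gene table ran from 33191622 to 151019342, with a mean of 67512490 ± 18985455 (SD, n = 67). These totals follow the deposited scale and are not read depths, so the depth behind a single value is unknown and no counting interval or floor is given. For printing, the deposited values were divided by 65.2264, which makes the geometric mean of the library totals that of a CPM table. The same factor was used for all libraries, so the authors' scaling was kept, and the results are called CPM.

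The choices of test, groups, thresholds, gene lists and naming rule were made before the data were examined. They foresaw raw counts, with a branch for normalised values, and that branch was used because the gene table holds no counts. The rules on duplicate libraries, mismatched columns and misplaced rows that follow were set after the data were seen and before any gene test was run.

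Of the 2211 pairs of gene-table libraries, 1 pair of healthy libraries was nearly identical. The robust SD of its log2 ratios over 4708 genes was 0.0165, against 0.219 for the next closest pair and 1.06 for the median pair. These 2 libraries were averaged and counted as 1 replicate, which left 66 replicates (22 healthy, 24 sMDS and 20 tMDS). The next closest pair was an sMDS and a tMDS library, and its 0.219 lay below 0.443, percentile 1 of all pairs. Whether this pair shares a donor was not tested, and both libraries were kept as separate replicates.

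Each isoform column was compared with the gene-table libraries through the genes shared by both tables. Of the 65 columns that could be assigned to a sample, 60 resembled the gene-table library of the same sample most. In 2 columns the correlation with another library was higher by more than 0.2, and these were left out. The remaining columns that resembled another library more were kept. An sMDS column had a correlation of 0.444 with its own library and 0.508 with a tMDS library. For a healthy column these were 0.525 and 0.612, the latter with another healthy library. The last such column belonged to the near-identical pair and resembled its partner. The other 2 columns of the isoform table carry the same name, could not be assigned to a sample and were not used. With the near-identical pair averaged, the isoform results rest on 21 healthy, 22 sMDS and 19 tMDS replicates.

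Out of place in part of the gene-table libraries were the values of 106 rows, against the same gene's isoform values or as a split into very low and very high values. Among them, 5 blocks of adjacent rows were found. With their neighbours, 283 rows were left out, of which 202 would have passed the filter. A further 36 rows with a repeated gene name were left out. XIST, TSIX and Y-linked genes were left out before testing. This left 20763 genes measured.

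Among the isoforms, 19 were at 0 in all 22 healthy columns and above 0 in over 90% of MDS columns, and 119 were at 0 in all 41 MDS columns and above 0 in over 90% of healthy columns. These 138 isoforms were left out of the isoform tests, and the 82 genes they belong to were left out of the tests of isoform shares.

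Genes at 1 CPM or more in at least 20 libraries were tested, which gave 12880 genes. The test was limma 3.58.1 in R 4.3.3 with trend and robust empirical Bayes on log2(deposited value + 1), and the Benjamini-Hochberg threshold was 0.05. Fold changes are on this scale, which understates the change of low values. All 3 groups shared 1 fit. MDS vs healthy was the mean of the sMDS and tMDS groups, weighted equally, minus healthy, and the other contrasts were tMDS minus sMDS, sMDS minus healthy and tMDS minus healthy. Isoforms with a mean of 1 FPKM or more were tested the same way on log2(FPKM + 1), which gave 16571 isoforms. Isoform shares were tested with limma on the log2 ratio of an isoform's FPKM to that of the gene's other isoforms, each with 0.5 added. They covered 8482 isoforms of 3297 genes with at least 2 isoforms at a mean of 1 FPKM or more. A share was called at an adjusted p under 0.05 and a difference of at least 10 percentage points, over libraries in which the gene summed to 1 FPKM or more. RefSeq names were matched to gene symbols for 45531 isoforms, or 91.5%.

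For the 22 gene lists, a library's score was the mean of log2(CPM + 1) over the list's measured members. Of 705 list genes, 677 had usable values, 19 had no row and 9 lay in rows left out. The list of mitochondrially encoded genes had no row, so 21 lists were tested. Differences of mean scores were tested with 2-sided permutation tests with 100000 resamples (smallest possible p 1e-05), adjusted with Benjamini-Hochberg over the 21 lists.

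Genes were named by a rule. For MDS vs healthy it took the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean of 8 CPM or more, a median that moved the same way, and a symbol that was not a placeholder, an antisense RNA or a pseudogene. From each of the 8 passing lists with the largest difference relative to the spread it took the 2 members with the smallest adjusted p in the list's direction. For tMDS vs sMDS, where no gene passed, it took the 5 genes with the smallest p. For isoform shares it took the 5 genes with the largest called difference.

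Alternatives to the scaling, filter, pseudocount, test, weights, covariates and libraries were fitted, and the group labels were redistributed over the same libraries 99 times for each comparison. Sample names fall into 3 naming styles. The most common style covers 9 of 23 healthy, 23 of 24 sMDS and 19 of 20 tMDS libraries and was used as a possible batch. Both near-identical libraries belong to it, so it holds 8 healthy replicates.

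Each test was checked on simulated data in which 200 genes or isoforms had been changed. The data had the real group sizes and each gene's mean and spread, the latter pooled over the groups. Genes were drawn independently and with the same spread in every group. Real libraries need not follow this, so the shares recovered may not carry over to them. For MDS vs healthy, 56% of genes changed 2-fold and 88% of genes changed 4-fold were recovered. For tMDS vs sMDS these shares were 47% and 87%. Among isoforms, 77% (2-fold) and 100% (4-fold) were recovered for MDS vs healthy, and 53% and 97% for tMDS vs sMDS. Among isoform shares, 31% and 79% were recovered for MDS vs healthy, and 17% and 74% for tMDS vs sMDS. These changes were made in the ratio of an isoform to the gene's other isoforms. The rule of at least 10 percentage points was not applied in this check, so the full rule can recover no more. List scores were simulated from a standard normal distribution. Of 500 such scores without a difference, 5.4% had a permutation p under 0.05, and of 200 scores shifted by 1 SD, 96.5% had. Other scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.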

Results

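RNA was sequenced from CD34-positive marrow cells, a population that holds blood-forming stem and progenitor cells, from healthy donors and from patients with myelodysplastic syndrome (MDS), a disorder of blood cell formation. The libraries formed 3 groups: 23 healthy, 24 sMDS and 20 tMDS. A pair of nearly identical healthy libraries was counted as 1 replicate, so the gene comparisons rest on 22 healthy and 44 MDS replicates. Per library, the deposited gene values summed to 69518856 ± 11177816 (SD, n = 23) in healthy, 72431367 ± 25768007 (SD, n = 24) in sMDS and 59302515 ± 14044390 (SD, n = 20) in tMDS. Hemoglobin genes took up to 43.8% of a library's total, and they took over 10% in 1 healthy, 7 sMDS and 2 tMDS replicates. Gene levels are given in CPM, here the deposited values divided by 1 factor for all libraries, and fold changes as differences of log2(deposited value + 1).

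The first comparison asks which genes differ between MDS and healthy CD34-positive cells. With limma at a Benjamini-Hochberg adjusted p under 0.05, 3121 of 12880 genes differed, of which 1135 were higher and 1986 lower in MDS. The direction split depended on scaling. Quantile normalisation gave 1468 higher and 1432 lower genes, and scaling each library to its own total gave 1172 higher and 1041 lower. Scaling to totals moved the median log2 fold change of all genes from -0.09 to 0.04. Within the most common naming style of the samples, which holds 8 healthy, 23 sMDS and 19 tMDS replicates, 212 genes passed, 140 higher and 72 lower, and 166 of them were also called over all libraries, each in the same direction. The filter of at least 20 libraries was kept there, so genes at 1 CPM or more in the 8 healthy replicates alone were not tested. That may shift this split towards higher genes. With naming style as a covariate 1561 genes passed, 767 higher and 794 lower.

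Genes of B-lymphoid precursors were lower in MDS. The score of the B-lymphoid progenitor list was 4.52 ± 0.95 (SD, n = 22) in healthy and 3.02 ± 1.02 (SD, n = 44) in MDS, a difference of -1.50 in log2 units. This difference had the smallest p the permutation test can give, 1e-05, with an adjusted p of 0.00021, and 40 of 44 MDS replicates lay below the healthy median. Camera, which compares a list with the other genes, gave this list an adjusted p of 0.213 with an estimated correlation, short of the threshold. Of its 28 tested members 19 were lower in MDS, and 23 were lower when p was adjusted over the list alone. VPREB3, a gene of precursor B cells, averaged 83.4 CPM ± 80.0 (SD, n = 22) in healthy, 34.6 ± 66.7 (SD, n = 24) in sMDS and 1.72 ± 2.52 (SD, n = 20) in tMDS. Few libraries carry the sMDS mean, and the medians were 65.9, 3.52 and 0.597 CPM. The log2 fold change of VPREB3 in MDS was -4.91 ± 0.77 (SE; limma adjusted p 6.6e-05), and 40 of 44 MDS replicates lay below the healthy median. The recombinase gene RAG2 fell by 4.83 on the log2 scale (SE 0.77, adjusted p 6.6e-05, lower in 42 of 44), but by 2.38 with a pseudocount of 1 CPM, which damps changes near 0. The B-cell transcription factor EBF1 fell by 4.41 (SE 0.72, adjusted p 7.71e-05, lower in 41 of 44). DNTT, which adds nucleotides during receptor rearrangement, fell by 4.46 (SE 0.88, adjusted p 0.000477, lower in 40 of 44). Outside this list, the neuropeptide gene NPY fell by 4.95 (SE 0.85, adjusted p 0.000127, lower in 38 of 44), but by 2.19 with that pseudocount. Within the most common naming style the list difference was -1.34 (permutation test, adjusted p 0.0215). DNTT (-3.73) and EBF1 (-2.94) kept their direction there but not their call, with limma adjusted p of 0.114 for each, and RAG2 and NPY were not tested there.

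**Figure D1:**
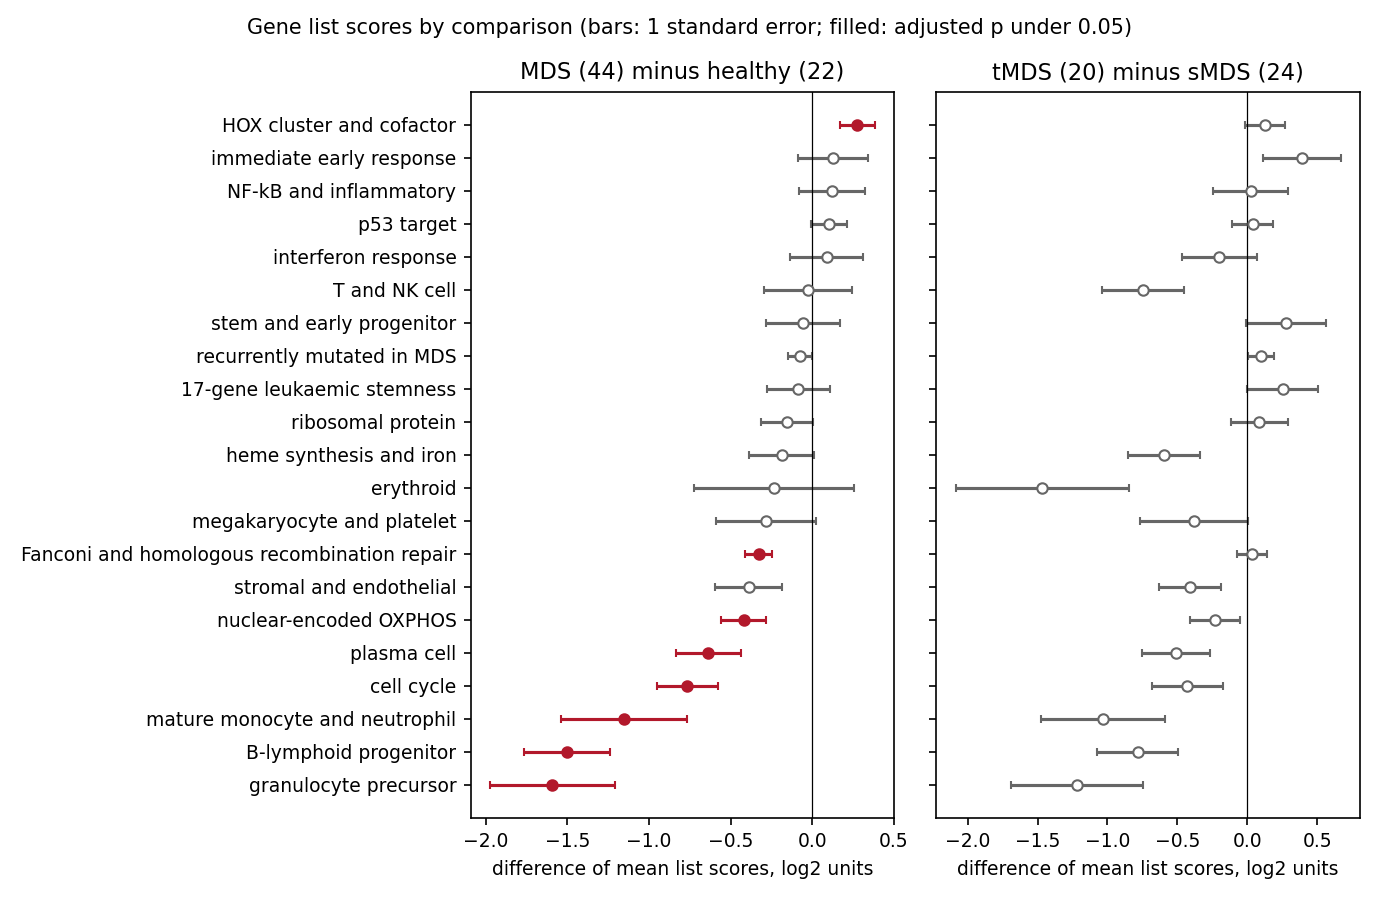
Difference in mean list score (log2 units, horizontal axis) for 21 gene lists, MDS minus healthy on the left and tMDS minus sMDS on the right. Bars are 1 standard error and filled points have an adjusted p under 0.05 in the permutation test, which 8 lists reached in MDS vs healthy and 0 in tMDS vs sMDS.

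Genes of the granulocyte line were lower as well. The granulocyte precursor list scored 7.30 ± 0.90 (SD, n = 22) in healthy and 5.71 ± 1.66 (SD, n = 44) in MDS, a difference of -1.59 (permutation test, adjusted p 0.00105; camera with an estimated correlation, 0.413), and 36 of 44 MDS replicates lay below the healthy median. Of its 26 tested members 19 were lower in MDS (21 adjusted over the list alone). The myeloperoxidase gene MPO averaged 7530 CPM ± 3660 (SD, n = 22) in healthy and 2700 ± 2830 (SD, n = 44) in MDS, a log2 fold change of -2.24 ± 0.40 (SE; limma adjusted p 0.000181), lower in 39 of 44. RNASE2 fell by 2.12 (SE 0.39, adjusted p 0.000262, lower in 35 of 44), and the neutrophil surface gene CD177 by 4.18 (SE 0.83, adjusted p 0.000477, lower in 36 of 44), or by 2.06 with a pseudocount of 1 CPM. CD177 averaged 24.7 CPM ± 39.6 (SD, n = 22) in healthy, 22.7 ± 48.2 (SD, n = 24) in sMDS and 0.262 ± 0.335 (SD, n = 20) in tMDS. Single libraries raise these means, and the medians were 7.23, 1.46 and 0.107 CPM. In sMDS alone the log2 fold change against healthy was -2.36, short of the threshold (adjusted p 0.118). The list of mature monocyte and neutrophil genes was lower by -1.15 (permutation test, adjusted p 0.0137; camera with an estimated correlation, 0.505; 33 of 44 below the healthy median), with 13 of 22 members lower (14 adjusted over the list alone), CSTA by -1.73 ± 0.43 (SE) and LILRB2 by -1.44 ± 0.40 (SE) among them. Within the most common naming style the granulocyte precursor difference was -1.79 (permutation test, adjusted p 0.0215) and the mature list difference -1.47 (permutation test, adjusted p 0.0485). MPO (log2 fold change -1.67, adjusted p 0.112), CSTA (-2.15, 0.0699) and LILRB2 (-1.06, 0.29) were not called there, and CD177 was not tested. LILRB2 was not called with naming style as a covariate either (-0.84, 0.27).

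Cell cycle genes were lower in MDS by -0.77 (5.99 ± 0.27 in healthy, SD, n = 22, against 5.22 ± 0.86 in MDS, SD, n = 44; permutation test, adjusted p 0.00115; camera with an estimated correlation, 0.413), and 39 of 44 MDS replicates lay below the healthy median. Of 43 members 31 were lower (34 adjusted over the list alone). MCM6, a subunit of the replicative helicase, averaged 126 CPM ± 27.4 (SD, n = 22) in healthy and 66.1 ± 29.4 (SD, n = 44) in MDS, and all 44 MDS replicates lay below the healthy median (log2 fold change -1.08 ± 0.18, SE; limma adjusted p 7.3e-05). MCM4 fell by 1.26 (SE 0.21, adjusted p 0.000122, lower in 43 of 44). The Fanconi and homologous recombination repair list was lower by -0.33 (permutation test, adjusted p 0.00115; camera, 0.505; 32 of 44 below the healthy median) with 10 of 30 members lower (11 adjusted over the list alone). FANCI fell by 1.27 (SE 0.22, adjusted p 0.000156) and RPA1 by 1.12 (SE 0.23, adjusted p 0.000845). Scaling to library totals left this list at -0.21, short of the threshold (adjusted p 0.245). In the most common naming style the cell cycle difference was -0.91 (permutation test, adjusted p 0.0224) and the repair list difference -0.30 (permutation test, adjusted p 0.0491). MCM4 (log2 fold change -0.79, adjusted p 0.143), FANCI (-0.76, 0.181) and RPA1 (-0.52, 0.383) were not called there.

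The plasma cell list was lower by -0.64 (permutation test, adjusted p 0.00811; camera with an estimated correlation, 0.505; 34 of 44 below the healthy median; 4 of 10 members lower, and 4 adjusted over the list alone), with FKBP11 at -1.01 ± 0.21 (SE) and IRF4 at -2.89 ± 0.61 (SE; -1.61 with a pseudocount of 1 CPM). The list of nuclear-encoded oxidative phosphorylation genes was lower by -0.42 (adjusted p 0.0136; camera, 0.541; 32 of 44; 24 of 60 members lower, and 35 adjusted over the list alone), with NDUFS1 at -0.87 ± 0.18 (SE) and UQCRQ at -0.63 ± 0.17 (SE). The HOX cluster and cofactor list was the 1 list that passed the threshold as higher in MDS, by 0.28 (adjusted p 0.0334; camera, 0.505; 32 of 44 above the healthy median; 4 of 17 tested members higher, and 4 adjusted over the list alone). HOXB3 rose by 1.72 ± 0.51 (SE; adjusted p 0.0124) and HOXA6 by 1.30 ± 0.41 (SE; adjusted p 0.0162), and both overlap antisense genes whose reads cannot be told apart. Under quantile normalisation the oxidative phosphorylation and HOX lists kept their direction, at -0.20 and 0.24, but missed the threshold (adjusted p 0.0889 for each). Within the most common naming style the differences of these 3 lists were -1.02, -0.64 and 0.43 (permutation tests, adjusted p 0.0215, 0.0244 and 0.0491). IRF4 (log2 fold change -2.89, adjusted p 0.0897), NDUFS1 (-0.45, 0.332), UQCRQ (-0.77, 0.0863) and HOXB3 (2.55, 0.0781) were not called there, and UQCRQ also missed the threshold under quantile normalisation (-0.39, adjusted p 0.0553).

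The 13 other lists differed by between -0.39 (stromal and endothelial) and 0.13 (immediate early response), with adjusted p of 0.139 or more. Among them the stem and early progenitor list differed by -0.06, the T and NK cell list by -0.03, the erythroid list by -0.23 and the ribosomal protein list by -0.16. These values were not stable: within the most common naming style the stem list differed by 0.59, the T and NK cell list by -0.72 and the stromal list by 0.05 (adjusted p 0.178, 0.168 and 0.91). The permutation test asks whether a list's score differs between groups. Camera with a preset correlation of 0.01 called 8 lists. With an estimated correlation it called 0, with a lowest adjusted p of 0.213 (B-lymphoid progenitor), so none of the preset calls held.

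**Figure D2:**
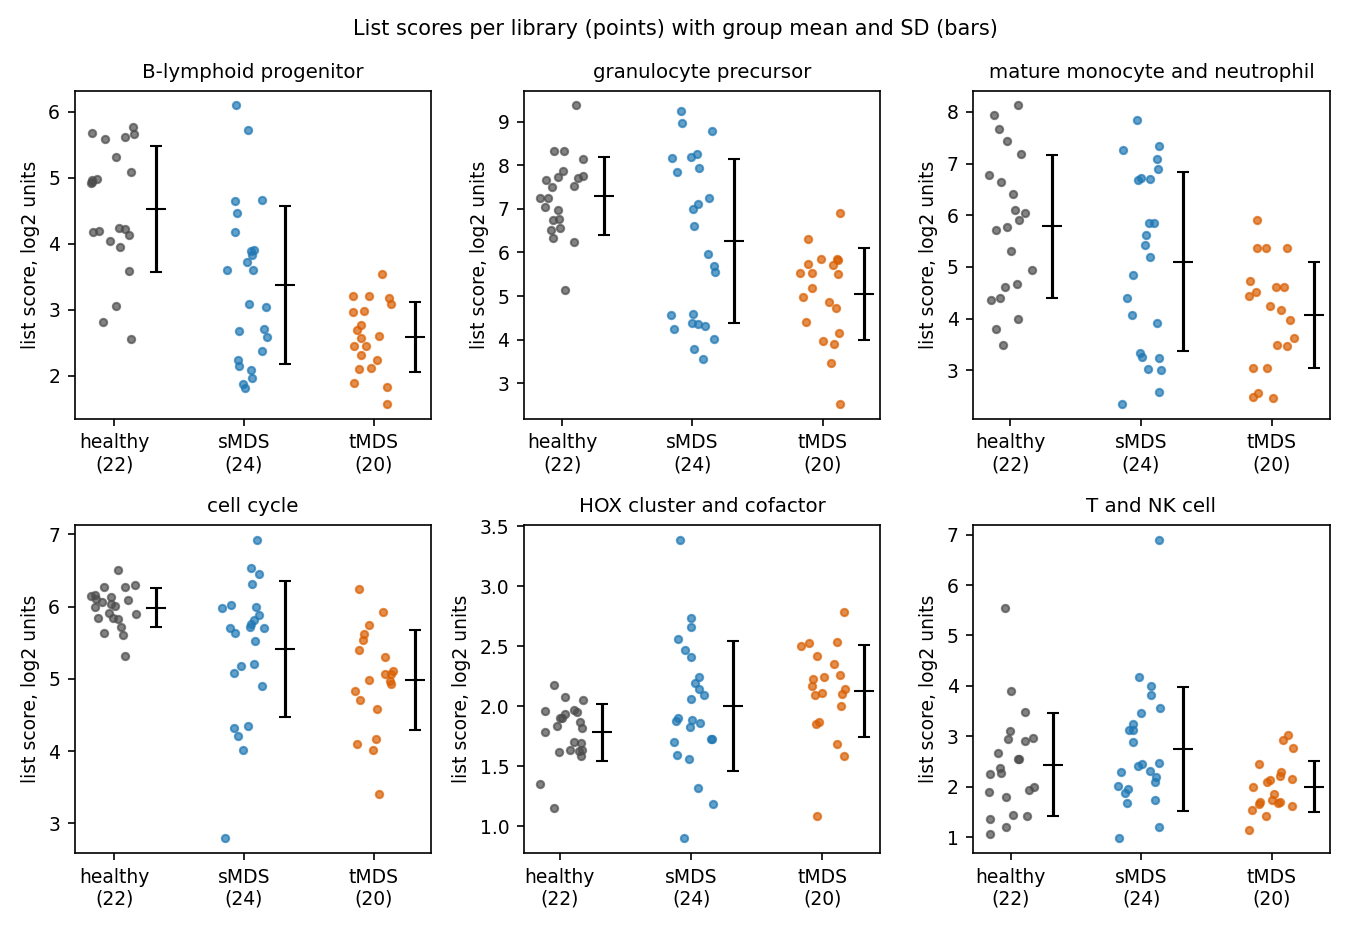
Scores of 6 gene lists (log2 units, vertical axis) in each of 22 healthy, 24 sMDS and 20 tMDS replicates, with the group mean and SD as bars. B-lymphoid progenitor scores averaged 4.52 in healthy, 3.38 in sMDS and 2.59 in tMDS, while the T and NK cell list did not pass the threshold in either comparison.

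Genes with the largest rise were near their lowest values in healthy libraries and spread widely in MDS. PRAME, a gene of the cancer-testis antigen class, averaged 0.2 CPM ± 0.255 (SD, n = 22) in healthy, 14.2 ± 37.5 (SD, n = 24) in sMDS and 37.9 ± 99.2 (SD, n = 20) in tMDS. Few libraries carry these means, and the medians were 0.0869, 0.637 and 5.19 CPM. For PRAME 34 of 44 MDS replicates lay above the healthy median (log2 fold change 3.85 ± 0.90, SE; adjusted p 0.00225), a change of 1.97 with a pseudocount of 1 CPM. The long noncoding RNA MEG3 rose by 3.63 (SE 0.83, adjusted p 0.00188, higher in 37 of 44; 1.81 with that pseudocount), from 0.618 CPM ± 0.919 (SD, n = 22) to 21.4 ± 58.0 (SD, n = 44), with medians of 0.124 in healthy, 1.29 in sMDS and 6.92 in tMDS. SH2D1A rose by 2.12 (SE 0.56, adjusted p 0.00552, higher in 35 of 44), but not past the threshold within the most common naming style (1.38, adjusted p 0.342) or with naming style as a covariate (1.66, adjusted p 0.116). GOLGA8A and GOLGA8B rose by 2.11 (SE 0.51) and 1.84 (SE 0.48). They are near-identical copies whose reads the counting may have split, so these values are uncertain, and neither was called within that naming style (2.42, adjusted p 0.09, and 1.89, adjusted p 0.142). In sMDS alone these 5 genes rose against healthy by 2.83, 2.72, 1.88, 1.45 and 1.40, short of the threshold (adjusted p 0.0909, 0.0814, 0.0748, 0.115 and 0.112, in the order named).

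**Figure D3:**
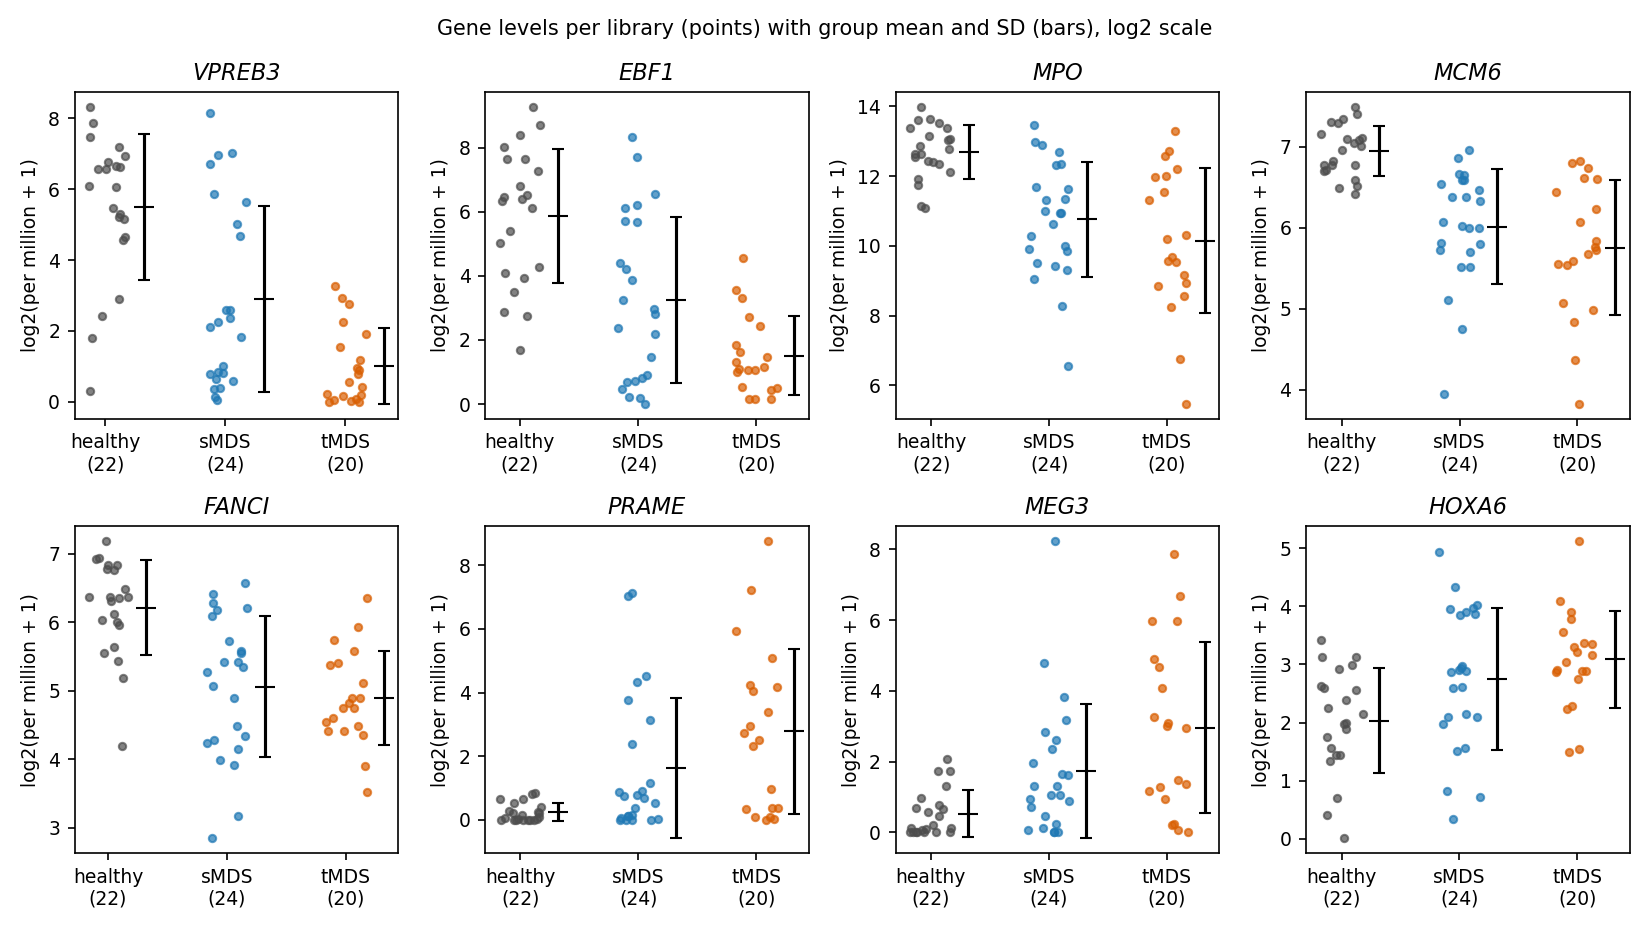
Levels of 8 genes (log2 of CPM + 1, vertical axis) in each of 22 healthy, 24 sMDS and 20 tMDS replicates, with the group mean and SD as bars. MCM6 lies below the healthy median in all 44 MDS replicates, whereas PRAME and MEG3 are high in part of the MDS replicates.

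The second comparison asks whether the sMDS and tMDS stages differ. It takes all replicates as independent, although a shared donor was not tested for the sMDS and tMDS libraries that resembled each other most. Limma called 0 of 12880 genes at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1245 genes, and the lowest adjusted p was 0.128. The unadjusted count depended on the setting. Without the replicates with over 10% globin it was 680 of 12572 genes, with a lowest limma adjusted p of 0.898. With libraries scaled to their totals it was 2120 of 12895 genes, with a lowest limma adjusted p of 0.104. The 5 genes with the smallest p are given as values. CTSE averaged 38.4 CPM ± 73.8 (SD, n = 24) in sMDS and 1.49 ± 1.79 (SD, n = 20) in tMDS (medians 6.45 and 0.666 CPM, as few libraries carry the sMDS mean; adjusted p 0.128), below the sMDS median in 20 of 20 tMDS replicates. PFKM (36.0 ± 23.1 and 17 ± 14.3), NFIA (141 ± 92.8 and 63.0 ± 45.6) and ADD2 (35.0 ± 46.0 and 9.63 ± 9.59) were lower in tMDS on average, and ZNF786 (2.30 ± 1.78 and 5.29 ± 4.86) was higher, each with an adjusted p of 0.333 (SD, n = 24 and 20).

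None of the 21 list scores passed in this comparison. The lowest adjusted p, 0.0866, was shared by 6 lists, all lower in tMDS: B-lymphoid progenitor (-0.78), erythroid (-1.47), granulocyte precursor (-1.22), mature monocyte and neutrophil (-1.03), T and NK cell (-0.75) and heme synthesis and iron (-0.60). Replicates with over 10% globin, 7 sMDS and 2 tMDS, were kept in these erythroid and heme differences. Camera with a preset correlation of 0.01 called 15 lists and with an estimated correlation 0 (lowest adjusted p 0.111). Adjusted over the list alone, 13 of 26 granulocyte precursor genes, 10 of 31 erythroid genes, 8 of 24 T and NK cell genes, 6 of 22 mature monocyte and neutrophil genes and 5 of 28 B-lymphoid progenitor genes were lower in tMDS, and 1 of 27 stem and early progenitor genes was higher. This adjustment takes no account of the 21 lists, and the members of a list need not vary independently. These counts therefore do not show that the stages differ.

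Against the healthy group each stage was also tested alone. For sMDS 381 genes differed, 79 higher and 302 lower, and for tMDS 3346 genes, 1327 higher and 2019 lower. Under quantile normalisation these became 59 higher and 99 lower for sMDS, and 1708 higher and 1585 lower for tMDS. Without the replicates with over 10% globin they were 2 higher and 15 lower for sMDS, and 905 higher and 1679 lower for tMDS. Scaling to totals gave 2048 higher and 901 lower genes for tMDS. With naming style as a covariate they were 32 higher and 12 lower for sMDS, and 1098 higher and 1155 lower for tMDS. For libraries of the most common naming style they were 4 higher and 0 lower for sMDS, and 291 higher and 208 lower for tMDS. Among genes named from the lists, RPA1, NDUFS1, UQCRQ, CSTA, LILRB2, HOXB3 and HOXA6 missed the threshold in sMDS vs healthy. Their limma adjusted p were 0.0641, 0.0538, 0.115, 0.0933, 0.287, 0.109 and 0.155, in the order named. The other genes named from the lists passed there, and all of them passed in tMDS vs healthy. The larger count for tMDS does not show that the stages differ, since the direct test between them called 0 genes.

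The isoform table was compared in the same way on 21 healthy, 22 sMDS and 19 tMDS replicates. In MDS vs healthy 1923 of 16571 isoforms passed, 831 higher and 1092 lower. In addition, 138 isoforms that were left out of the test are listed at 0 in every column of 1 side, so the isoform values of the healthy and MDS columns differ in a way that follows the groups. Quantile normalisation gave 1343 higher and 1310 lower isoforms. With naming style as a covariate 129 higher and 29 lower isoforms passed, and within the most common style 0 higher and 3 lower. Of these 3, 1 belongs to HINT1, whose isoforms summed to 0 in all MDS columns. The exclusion thus did not remove every isoform at 0 on 1 side. Isoform shares passed for 181 of 3297 genes, but for 0 genes within the most common naming style (559 isoforms at an unadjusted p under 0.05) and for 0 with the covariate (905 at an unadjusted p under 0.05). The largest called differences were in VIM-AS1, THBS3, SUCO, DGCR8 and IKBKB. For example, 1 of the isoforms of SUCO held 61.8% ± 31.2 (SD, n = 21) of the gene's FPKM in healthy, 21.8% ± 26.8 (SD, n = 22) in sMDS and 23.7% ± 28.7 (SD, n = 19) in tMDS (limma adjusted p 0.005828 for MDS vs healthy). An isoform of THBS3 held 4.01% ± 14.3 (SD, n = 18) in healthy, 41.7% ± 31 (SD, n = 12) in sMDS and 44.7% ± 35.0 (SD, n = 17) in tMDS (limma adjusted p 0.006778 for MDS vs healthy). VIM-AS1 overlaps VIM on the other strand. Between tMDS and sMDS limma called 0 isoforms (1687 at an unadjusted p under 0.05) and 0 genes by isoform share (556 isoforms at an unadjusted p under 0.05).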

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

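Alternatives chosen only after the data were seen are those on misplaced rows, near-identical and close libraries, globin-rich libraries, a pseudocount of 1 CPM, scaling to library totals, quantile-normalised list scores, mismatched isoform columns and isoforms at 0 on 1 side. The comparison without libraries of low total counts was not run, since the table holds no counts. The cause of a change was not tested unless it is named.

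The count of 3121 genes in MDS vs healthy stayed within 1.5 times under 11 of 14 alternatives. It was 1561 with naming style as a covariate, 212 within the most common naming style and 2080 without the replicates with over 10% globin. For the 212 genes, having fewer libraries may explain the smaller count: 81 of 100 random subsets with the same group sizes gave as few genes (median 3, highest 1003). These subsets cannot exclude a part of naming style, since 1561 genes passed over all libraries with the style as a covariate. The tMDS vs healthy count of 3346 fell to 499 within that style, where 81 of 100 such subsets gave as few.

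The sMDS vs healthy count of 381 moved under 7 of 14 alternatives. It was 158 under quantile normalisation, 178 without a filter, 44 with naming style as a covariate, 4 within the most common style (KIAA1107, TRIM39, APOL1 and AGAP6, named after their values were seen) and 17 without globin-rich replicates. It was 775 when only the groups compared entered the fit and 671 with array weights.

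Between tMDS and sMDS the count of genes stayed at 0 except for 1 gene without a filter (AGR2) and 1 gene, CTSE, without the pair of an sMDS and a tMDS library that resembled each other most. CTSE then had a log2 fold change of -3.61 and an adjusted p of 0.00458, against 0.128 with all libraries. Its highest sMDS values, 345, 113 and 109 CPM, came from globin-rich replicates (14.9%, 11.7% and 43.8% globin). Another sMDS replicate with 18.6% globin held 4.17 CPM. Without the replicates with over 10% globin, the lowest limma adjusted p of any gene tested was 0.898. The count of isoforms was 0 except for 1 isoform of MRS2 without a filter, and the count of isoform shares was 0 in all 7 alternatives. These few were named after their values were seen.

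The 1923 isoforms of MDS vs healthy became 158 with naming style as a covariate and 3 within the most common style, of which 2 belong to RPSA and HINT1 and 1 matched no symbol. The 4 isoforms of HINT1 summed to 0 in all MDS columns, so its call is of the kind that the exclusion of isoforms at 0 on 1 side was meant to remove. That exclusion was therefore not complete, and the 1923 may hold more such isoforms. The 181 genes with a changed isoform share became 110 with an offset of 0.1, 48 at a mean of 5 FPKM, where fewer isoforms were tested, 102 at a minimum of 20 points, a stricter rule by construction, 0 with the covariate and 0 within the most common style.

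List scores passed for 8 lists in MDS vs healthy and for 6 to 10 under the other permutation settings, but for 0 with camera and an estimated correlation. In tMDS vs sMDS no list passed except under camera with a preset correlation of 0.01, which called 15.

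No named gene changed sign in MDS vs healthy, and no list that passed in either setting did. Lists short of the threshold in both did change sign, such as the stem list (-0.06 to 0.59 within the most common style). Of 344 alternatives for the 25 genes named in MDS vs healthy, 326 kept the call and 18 lost it. Within the most common naming style 15 of the 21 genes tested lost it and 6 kept it (MEG3, VPREB3, RNASE2, MCM6, FKBP11 and HOXA6), which kept it in all 14. The 4 others, PRAME, NPY, CD177 and RAG2, were not tested in that style and kept the call wherever they were tested. Of 126 alternatives for list scores with the permutation test, 121 gave the same verdict. The OXPHOS and HOX lists lost it under quantile normalisation and the Fanconi list when scaled to totals, and the erythroid (-0.92) and heme (-0.48) lists passed without globin-rich replicates. Globin is itself an erythroid product and 9 of the 10 replicates removed were MDS, so that shift follows from the removal and says nothing about the groups. No depth is known for these values, so what depth limits could not be measured.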

Other observations

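The tests on redistributed labels, on the B-lymphoid progenitor list, on isoforms at 0 and on eosinophil genes were chosen only after the result was seen, and that on random subsets before. The test on nuclear-retained RNAs was chosen after MEG3, NEAT1 and KCNQ1OT1 had been seen to rise, but before its own score was computed.

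The group labels were redistributed over the same libraries, 100 arrangements with the real one. For MDS vs healthy 1 of 100 arrangements, the real one, gave as many as 3121 genes (highest of the others 1). For sMDS vs healthy it was 1 of 100 for 381 genes (highest of the others 343), and for tMDS vs healthy 1 of 100 for 3346 genes (highest of the others 1). For isoforms in MDS vs healthy it was 1 of 100 for 1923 (highest of the others 106), and for isoform shares 1 of 100 for 181 (highest of the others 9). None of the other arrangements reached any of these 5 counts. For sMDS vs healthy the margin was small, 343 against 381, so chance is not excluded for that count. The arrangements also do not separate the groups from naming style, which is unevenly spread over them. With naming style as a covariate, 44 genes passed in sMDS vs healthy. In MDS vs healthy 158 isoforms and 0 genes by isoform share passed with it. For tMDS vs sMDS all 100 arrangements gave as many as the real counts of 0, for genes (highest of the others 878), isoforms (highest of the others 436) and isoform shares (highest of the others 96), with a median of 0 in each. With a real count of 0 no other outcome was possible, so this says nothing about whether the stages differ. An arrangement that calls 878 genes points to a structure among the MDS libraries, whose source was not tested.

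The lower score of the B-lymphoid progenitor list in MDS was weighed against technical explanations. It is not explained by naming style alone, since the difference within the most common style was -1.34 (SE 0.40). Globin-rich libraries and scaling do not account for it, since it was -1.59 without replicates over 10% globin and -1.40 with libraries scaled to their totals, against -1.50. A larger share of mature myeloid cells in the MDS libraries would raise mature myeloid genes, but that list was lower by -1.15 (SE 0.39). Other CD34-negative cells are not covered by this list, so a larger share of those stays open. Fewer carried-over cells of every other type would lower T and NK cell genes alike. The T and NK score minus the B-lymphoid score was higher in MDS by 1.48 (SE 0.28) over all libraries, but by 0.63 (SE 0.42) within the most common naming style, where the T and NK list differed by -0.72 (SE 0.41). The plasma cell list (-0.64, SE 0.20), the mature myeloid list and, short of the threshold, the stromal list (-0.39, SE 0.20) were lower over all libraries too, so this explanation stays open. Also open are a loss that is specific to carried-over B-lineage and myeloid precursors, handling of the RNA, since nuclear-retained RNAs were higher in MDS by 0.77, the age of donors, which no label gives, and a smaller share of B-lymphoid progenitors among the CD34-positive cells in MDS. The last may be offered as a hypothesis only, since bead enrichment above 90% leaves room for other cells and the sorting was not measured in these tables. CD34 itself, looked up after the tests, averaged 360 CPM ± 225 (SD, n = 22) in healthy, 274 ± 226 (SD, n = 24) in sMDS and 458 ± 355 (SD, n = 20) in tMDS (limma adjusted p 0.525 for MDS vs healthy).

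The gene count was smaller within the most common naming style. In 81 of 100 random subsets of the same group sizes, as few genes passed, so fewer libraries may explain the smaller count.

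Isoforms listed at 0 in every column of 1 side were in part abundant on the other: 10 of 19 at 0 in healthy and 52 of 119 at 0 in MDS had a mean over 50 FPKM there. The tests cover these alone. Of the 50 genes with such an isoform at a mean over 50 FPKM on the other side, 100% had a gene-table mean of 8 CPM or more on the side listed at 0. RPS13, for example, is at 0 in the MDS isoform columns and averaged 1290 CPM ± 681 (SD, n = 44) in the MDS gene-table libraries. For genes with several isoforms in the table, the values argue against a switch to other isoforms of the same genes: the other isoforms summed to 1 FPKM or more in 0% of the 50 genes. For 26 of the 50, which have 1 isoform in the table, that outcome was fixed in advance and says nothing about a switch. A candidate explanation is that healthy and MDS isoform values were estimated in separate runs, each of which failed at some abundant genes. It follows the groups, so a difference between isoform runs and a difference between healthy and MDS cells cannot be separated in the isoform table.

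Among the genes that rose in MDS were the nuclear noncoding RNAs MEG3, NEAT1 and KCNQ1OT1. A list of 18 other RNAs known to stay in the nucleus was written after these had been seen and before its score was computed. Its 16 measured members scored higher in MDS by 0.77 (5.92 ± 0.32 in healthy, SD, n = 22, and 6.68 ± 1.01 in MDS, SD, n = 44; 2-sided permutation p 0.00073), above the healthy median in 31 of 44 MDS replicates. Of these 16 genes 12 were higher and 0 lower at a limma adjusted p under 0.05. The idea came from the same libraries, so these values are not an independent check of it. The difference was 0.99 (SE 0.37) within the most common naming style and 0.89 (SE 0.28) with libraries scaled to totals. Nuclear RNA may therefore take a larger share in part of the MDS libraries. Whether this comes from the cells or from handling of the aspirates was not tested, and handling stays open for the lower cell cycle, repair and OXPHOS scores too.

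The eosinophil granule genes EPX and PRG3 fell in MDS. A list of 16 other eosinophil, basophil and mast cell genes, written after these had been seen, scored lower by -0.60 (2-sided permutation p 0.00608), in 33 of 44 MDS replicates below the healthy median. However, 5 of its genes also belong to the other lists, mostly to the granulocyte precursor list. Without them the difference was -0.26 (SE 0.20), so a fall of this class apart from the granulocyte genes could not be shown.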
